A study of Mus musculus with 15 samples.

How the data were processed

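RNA was measured in 15 libraries of spermatogonia sorted by flow cytometry for the Pou5f1-GFP (Oct4-GFP) transgene from mouse testes. The donors were wild type (WT) or carried a null allele of Akt1s1 (KO), and were 3 days old, 7 days old or 2 to 3 months old (adult). The labels give 3 WT and 2 KO libraries at 3 days post partum (dpp), 2 WT and 3 KO libraries at 7 dpp, and 2 WT and 3 KO libraries in adults. Per the labels' protocols, testes were dissociated with collagenase, DNase I and trypsin, small batches of cells were sorted, and poly(A) RNA libraries were made with a kit from Vazyme and sequenced on a HiSeq. Libraries are named here by the number in their title. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

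The deposited values are a signal per gene, one column per library and 27128 gene names per column. Per the submitters' processing notes, Trim Galore, kallisto, DESeq2 and the mouse build mm10 were used, with versions, order and annotation not given in the sources used here. The authors' values were tested for their unit: in each library all values between 0 and 1 were whole multiples of 0.01 after division by the factor that brings a column to a total of 1e6, within a tolerance of 0.0006. Each deposited signal therefore behaves as a TPM value with 2 decimals times a single factor per library. Column totals ran from 896543 in adult KO library 12 to 1183294 in 3 dpp KO library 16, and the totals of the KO libraries at 3 dpp (1183294 and 1178330) were above those of the WT libraries of that age (1002649 to 1086085). TPM keeps no read number, so the depth per library is unknown and no counting interval can be given. Between 14515 and 16312 genes had a signal of at least 1 per library, and the 10 highest genes held 4.1% to 8.2% of the signal, the highest share being that of 3 dpp KO library 18. An exact 0 can be a failed estimate in such values, so a group at 0 is described as listed at 0.

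The design had been written for counts, with a branch for other units. Because the deposited signal is not a count, that branch was used: limma-trend on log2(signal + 1), for genes with a signal of at least 1 in at least 2 libraries. Of the 27128 names, 2582 were at 0 in every library and 17746 were tested. Fold changes are on the log2(signal + 1) scale, which understates the change of genes with low signal. All 15 libraries entered a single model with a mean for each of the 6 groups (9 residual degrees of freedom, prior 4.25), and p-values were adjusted with the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were KO against WT at each age and averaged over the ages with equal weight, 7 dpp against 3 dpp and adult against 7 dpp within each genotype, and the 3 differences of the genotype effect between ages (interaction contrasts). Fold changes are given as log2 values ± their standard error (SE), group levels as the mean signal ± SD. Adjusted p-values are those of limma unless another test is named. R 4.3.3 and limma 3.58.1 were used.

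The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named per genotype comparison were Akt1s1 and Pou5f1, the 12 highest and 12 lowest fold changes (8 and 8 for age comparisons, 6 and 6 for interactions) among genes that passed the threshold, had a mean signal of at least 5 over the 15 libraries and showed no overlap between the libraries compared, and up to 4 members with the smallest p from each gene list. For averaged comparisons the genotype effect had to have the same sign at each age, and for interactions opposite signs at the ages compared. Where fewer than 6 genes passed in a direction, the next by p were named up to 6 as values that did not pass. Provisional gene models (Gm, Rik, LOC, accession-like and pseudogene names, and any name not found in the gene annotation) were counted, not named.

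Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists of a comparison, with an estimated correlation and fry as alternatives. The lists were mTOR pathway components, sterol and fatty acid synthesis, glycolysis, the amino acid stress response (ATF4 targets), cytosolic ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, lysosome and autophagy, undifferentiated spermatogonia, differentiating spermatogonia, prospermatogonia, meiotic prophase, round and elongating spermatids, Sertoli cells, Leydig cells, peritubular myoid cells, stromal fibroblasts, macrophages, endothelial cells, erythroid cells, cell cycle, immediate early and dissociation stress genes, and p53 targets. A further list of 13 mitochondrially encoded transcripts had 0 members in the files and was not tested. Across the 8 genotype and age comparisons, 66 of 184 list tests passed at the preset correlation and 0 with an estimated correlation, while fry called 43, of which 29 were among the 66 in the same direction. In camera the list calls below therefore hold at the preset correlation only, and the adjusted p with an estimated correlation is printed with them. A list score per library is the mean over the members of log2(signal + 1) centred on each gene's mean.

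The fit was tested on simulated data in which 200 genes were changed by known amounts. For KO against WT at 3 dpp, among 16948 genes tested, 40.3% of the genes changed by a log2 of 0.5 were recovered, 80.6% of those changed by 1 and 97% of those changed by 2, with 9 false calls. The shares were 37.3%, 86.6% and 98.5% at 7 dpp (16932 genes, 9 false calls) and 44.8%, 83.6% and 98.5% in adults (16939 genes, 7 false calls). In 20 simulated runs in which a list was shifted by 0.4, camera found it 20 times with 0 false lists both at the preset and at the estimated correlation, and fry found it 20 times with 7 false lists. Genes varied independently in these runs, so they do not test the preset correlation on lists whose genes move together. In the real libraries the estimated correlation was, for example, 0.54 for ribosomal proteins and 0.738 for macrophages.

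The alternatives were quantile normalization, no filter and a stricter filter on low values (at least 5 in 2 libraries), limma without the mean-variance trend, a pseudocount of 0.1, a fit of only the libraries compared, a test against a fold change of 1.5, and leaving out each library. Chosen after seeing the data were values rescaled to the same total per library, removal of each library's trend with transcript length or with length and GC content, leaving out chromosomes 8 and 14, and leaving out the 3 dpp libraries. Removal of a trend also sets the mean over all genes with a length to the same value in each library. Counts and splits that change in these settings can therefore reflect this centring as well as length. Gene positions, lengths and GC contents came from an mm10 annotation matched by symbol, lengths and GC contents being medians over a gene's transcripts. Such a median can differ from the length of the expressed transcript. It was 869 bases for Fasn, 582 for Cenpe and 2529 for Ndufb7. A gene that passes with the trends removed is therefore not shown to be free of a length effect. Of the names, 15697 were current symbols, 5027 older symbols and 6404 unmatched, and 22 had been turned into dates by a spreadsheet. Of the 17746 tested genes, 15135 (85.3%) had a length.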

Results

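Transcript levels were measured in spermatogonia sorted from mouse testes by the green fluorescence of a Pou5f1-GFP transgene, which marks early germ cells. The mice were WT or carried a null allele of Akt1s1. This gene encodes PRAS40, a component of the mTORC1 kinase complex that binds raptor and restrains its activity. The 15 libraries comprised 3 WT and 2 KO libraries at 3 dpp, 2 WT and 3 KO libraries at 7 dpp, and 2 WT and 3 KO libraries of adults aged 2 to 3 months. The depth of the libraries cannot be read from the deposited signal. The first principal component held 61.2% of the variance and set the adult libraries (64.3 to 100.1) apart from those of both younger ages (-57.7 to -23.2). The second held 12.3% and parted 3 dpp (-44.0 to -9.2) from 7 dpp (17.1 to 44.0). Libraries of the same group correlated across genes with r between 0.973 and 0.989, the lowest pairs lying in the KO groups at 3 dpp (0.974) and in adults (0.973). Library numbers run in blocks by age, and within each age the WT numbers come before the KO numbers. The labels do not say whether the numbers mark collection or batches, so an effect of order cannot be told apart from age or genotype.

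Akt1s1 transcript was lower in every KO library than in every WT library of the same age. The gene lies on chromosome 7 (mm10, 44848991 to 44855421, plus strand), with 4 exons in its longest transcript. Its signal was 52.4, 51.0 and 49.4 in WT and 35.2 and 33.4 in KO libraries at 3 dpp. It was 54.5 and 72.9 against 39.8, 39.5 and 37.2 at 7 dpp, and 67.9 and 67.1 against 43.1, 45.2 and 47.4 in adults. On the log2 scale it fell by 0.56 ± 0.10 (SE) at 3 dpp, 0.69 ± 0.10 at 7 dpp and 0.57 ± 0.10 in adults (limma adjusted p = 0.00653, 0.0169 and 0.0411). Averaged over the ages it fell by 0.60 ± 0.06 (adjusted p = 9.03e-05). Substantial Akt1s1 transcript therefore remained in KO libraries. Since the deleted part of the gene is not given, its level does not check the allele itself. Without single libraries the adjusted p rose to 0.051 at 3 dpp (without KO 18), and to 0.13, 0.053 and 0.088 at 7 dpp (without WT 3, KO 5 and KO 6). In adults it rose to 0.45, 0.075, 0.15 and 0.097 (without WT 7, WT 9, KO 11 and KO 12), while the averaged change passed without any of the 15. Pou5f1, whose promoter drives the sorting marker, did not pass between genotypes at any age. Its log2 differences were -0.28 ± 0.38 at 3 dpp, -0.73 ± 0.38 at 7 dpp, -0.72 ± 0.38 in adults and -0.57 ± 0.22 averaged (adjusted p = 0.704, 0.716, 0.493 and 0.229).

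**Figure D1:**
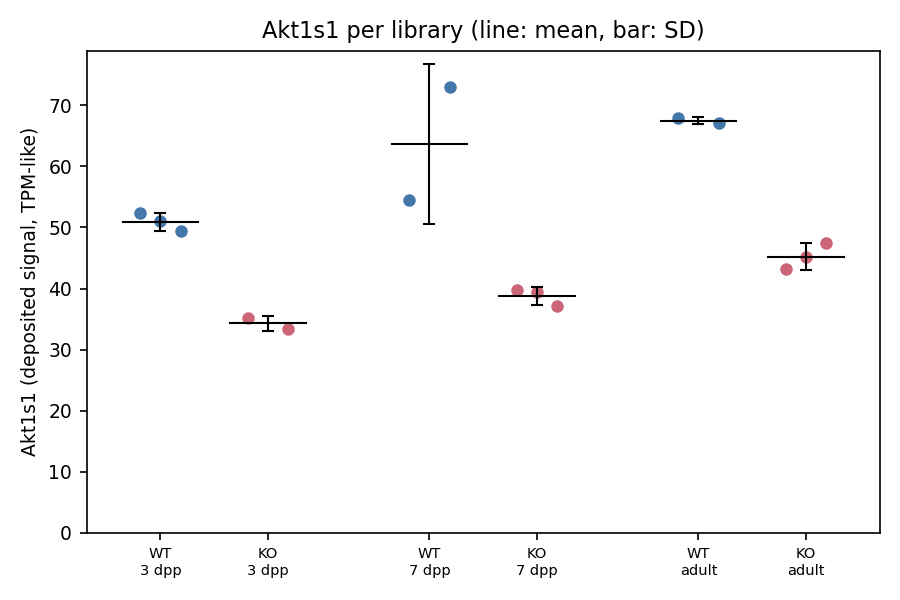
Signal of Akt1s1 (vertical axis) in each of the 15 libraries, by age and genotype, with points for libraries, a line for the group mean and a bar for the SD. All KO libraries, at 33.4 to 47.4, lie below the WT libraries of their own age.

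At 3 dpp, transcripts of the protein synthesis and respiration machinery were higher in KO than in WT cells, while single genes of the mTOR pathway, of fatty acid synthesis and of meiotic prophase were lower without a call of their lists. Of 75 cytosolic ribosomal protein genes tested, 34 rose and 0 fell (62 and 1 when adjusted over the list alone). Rpl29 went from a signal of 1383 ± 74.4 (SD, n = 3) to 2120 ± 42.4 (n = 2), with a log2 change of 0.62 ± 0.12, and Rpl35a (0.58 ± 0.11). Of 75 genes of oxidative phosphorylation, 29 rose and 1 fell (51 and 1 over the list alone). Cox7a2 and Atp5o, subunits of complex IV and of ATP synthase, rose by 0.74 ± 0.09 and 0.82 ± 0.11. The complex I subunit gene Ndufb7 went the other way and fell by 0.81 ± 0.08. The median log2 change was 0.43 in the ribosomal protein list and 0.38 in the oxidative phosphorylation list (camera adjusted p = 1.84e-24 and 2.92e-23), with adjusted p = 0.67 and 0.66 with an estimated correlation. With fry the adjusted p was 0.033 and 0.024. Quantile normalization took the ribosomal protein median to 0.00 and ended its call (adjusted p = 0.40), whereas it lowered the oxidative phosphorylation median to 0.16, with the list still called (7.9e-07). It gives every library the same distribution of values. A shift shared by many genes of high signal, such as Rpl29, can thus be removed by it. With each library rescaled to the same total, the median over all tested genes shifted to -0.18. The medians of the ribosomal protein and oxidative phosphorylation lists were then 0.24 and 0.19, which lay 0.42 and 0.37 above it. Across all genes with a known length, the change in KO at 3 dpp fell with transcript length, with medians of 0.06, 0.05, 0.00, -0.08 and -0.19 in groups of 3027 genes from the shortest to the longest (Spearman's rho = -0.29 across genes, which are not independent replicates). The ribosomal protein and oxidative phosphorylation genes are short (median lengths of 628 and 607 bases, against 1407 for all genes). With length and GC trends removed, 3 ribosomal protein genes were higher and 0 lower, and 7 of oxidative phosphorylation were higher and 1 lower, while both medians were 0.33 and both lists were called (camera adjusted p = 1.1e-14 and 7.6e-15). Rpl35a, Cox7a2, Atp5o and Ndufb7 passed in this setting and Rpl29 did not (0.50 ± 0.14, adjusted p = 0.0588).

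Among 26 mTOR pathway components at 3 dpp, 2 rose and 6 fell, the targeted Akt1s1 among the latter (3 and 8 when adjusted over the list alone). Pdpk1, which encodes the kinase PDK1 that activates AKT, fell by 1.12 ± 0.19, from a signal of 32.7 ± 2.87 to 14.9 ± 5.34, and Rptor, the scaffold raptor of mTORC1, fell by 0.47 ± 0.11. Lamtor1, part of the complex that anchors mTORC1 to lysosomes, rose by 0.74 ± 0.14. Of 26 genes of sterol and fatty acid synthesis, 4 fell and 0 rose (the same numbers over the list alone). Acaca and Fasn, which build fatty acids, fell by 0.77 ± 0.09 and 0.38 ± 0.10, the desaturase gene Scd2 by 0.70 ± 0.16, and Acly, which supplies acetyl-CoA, by 0.27 ± 0.07. The glycolysis list had 2 genes up and 1 down of 17 (also over the list alone), with Hk2 down by 0.81 ± 0.15 and Eno1 up by 0.51 ± 0.14. Ribosome biogenesis had 3 up and 1 down of 30 (4 and 3 over the list alone). The rRNA methyltransferase gene Fbl rose by 0.48 ± 0.10 and Polr1a, the large subunit of RNA polymerase I, fell by 0.34 ± 0.09. None of 19 amino acid stress response genes passed (0 higher and 0 lower in limma, with 4654 of 17746 genes at an unadjusted p under 0.05), their median of 0.10 and mean of -0.06 differing in sign. As lists these 5 did not pass at the preset correlation (camera adjusted p = 0.476 to 0.966). These counts changed when the trends were removed, a setting that also removes each library's mean over all genes. With length and GC trends removed, 1 mTOR gene was higher and 3 lower (Akt1s1 among them), 3 genes of sterol and fatty acid synthesis were lower, 1 of glycolysis was lower and 0 of ribosome biogenesis passed. Pdpk1 (-1.04 ± 0.19), Rptor (-0.39 ± 0.10, adjusted p = 0.0499), Lamtor1 (0.68 ± 0.16), Acaca (-0.76 ± 0.10), Fasn (-0.48 ± 0.09), Scd2 (-0.52 ± 0.14) and Hk2 (-0.81 ± 0.15) passed in this setting. Acly, Eno1, Fbl and Polr1a did not (adjusted p = 0.152, 0.118, 0.116 and 0.0684). The lengths used are medians over transcripts (1058 bases for Acaca and 869 for Fasn), so passing in this setting does not exclude a length effect.

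Germ cell programs at 3 dpp moved in few genes. Of 31 genes of meiotic prophase, 6 fell and 0 rose (6 and 0 over the list alone). They included the synaptonemal complex genes Sycp1 (-0.69 ± 0.11) and Sycp2 (-0.76 ± 0.14), the cohesin gene Smc1b (-0.50 ± 0.09) and the transcription factor gene Mybl1 (-1.23 ± 0.22). The list did not pass (camera adjusted p = 0.205). With length and GC trends removed 3 of its genes were lower, Sycp2 (-0.49 ± 0.13), Meioc (-0.92 ± 0.23) and Mybl1 (-1.10 ± 0.21), while Sycp1 (-0.40 ± 0.12) and Smc1b (-0.28 ± 0.10) did not pass (adjusted p = 0.0696 and 0.128), and its median was 0.02. Of 27 cell cycle genes, 5 fell and 1 rose (also over the list alone), its median of 0.04 and mean of -0.06 differing in sign. The kinetochore genes Cenpe and Cenpf fell by 0.74 ± 0.10 and 0.61 ± 0.10 and Mki67 by 0.66 ± 0.13. In the same setting 2 cell cycle genes were lower, Cenpe and Cenpf, and 1 higher, and Mki67 did not pass (-0.38 ± 0.12, adjusted p = 0.0893), nor did Nanos3 and Taf4b, named next (0.0855 and 0.875). Of 29 genes of undifferentiated spermatogonia, Nanos3 rose by 1.07 ± 0.30 and Taf4b fell by 0.34 ± 0.08 (0 higher and 1 lower over the list alone). Of 12 genes of differentiating spermatogonia 0 passed, and of 10 prospermatogonial genes Dnd1 rose by 0.36 ± 0.10. Among 14 p53 targets the apoptosis genes Bax and Pmaip1 rose by 0.43 ± 0.10 and 1.43 ± 0.42. With length and GC trends removed Pmaip1 passed (1.69 ± 0.40, adjusted p = 0.0353), but Bax (0.31 ± 0.12, 0.168) and Dnd1 (0.35 ± 0.12, 0.1) did not. The lysosome and autophagy list was called higher (median 0.14, 1 of 31 genes up, camera adjusted p = 0.0357, but adjusted p = 0.97 with an estimated correlation). With rescaled values its median was -0.05, above the -0.18 of all genes, and the call ended (0.49). It also ended with quantile normalization (0.39), with a stricter filter (0.063), in a fit of the libraries of this age alone (0.056), without WT 13 (0.051), WT 14 (0.087) or KO 16 (0.16), and with the length trend or length and GC trends removed (0.056 and 0.23).

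Markers of other testis cells were measured in the same libraries at 3 dpp. The Sertoli cell list was lower in KO (median -0.60, camera adjusted p = 0.0478, and adjusted p = 0.97 with an estimated correlation), with Kitl down by 1.24 ± 0.35 and 0 of 19 genes passing over the list alone. This rested on KO 16, where Amh, a Sertoli cell hormone, had a signal of 55.8 against 277 in KO 18. Without KO 16 the median was 0.16, and without WT 13 or WT 14 the adjusted p was 0.099 or 0.11. The call also ended with a stricter filter (0.14), a pseudocount of 0.1 (0.068), rescaled values (0.35) and in a fit of the libraries of this age alone (0.11). Of 7 endothelial genes Egfl7 rose by 0.55 ± 0.14, and of 17 immediate early and dissociation stress genes Hspa1a fell by 0.78 ± 0.23 (0 over the list alone). With length and GC trends removed Kitl (-1.20 ± 0.33), Egfl7 (0.43 ± 0.13) and Hspa1a (-0.70 ± 0.25) did not pass (adjusted p = 0.0578, 0.0835 and 0.126). In limma no gene passed of the lists of macrophages (median 0.47), Leydig cells (-0.69), peritubular myoid cells (0.11), stromal fibroblasts (-0.26), spermatids (0.07) and erythroid cells (0.21).

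The strongest single changes at 3 dpp were in other genes. The tyrosine kinase gene Ptk2b rose from a signal of 2.76 to 21.4 (means, log2 change 2.61 ± 0.22, adjusted p = 3.6e-05), Tom1, an adaptor of endosomal sorting, rose by 4.04 ± 0.79, and Cdc42ep3, an effector of CDC42, by 1.69 ± 0.28. The enolase gene copy Eno1b fell by 5.36 ± 0.30, the transketolase-like gene Tktl2 by 3.56 ± 0.21, the lipoprotein lipase gene Lpl by 2.67 ± 0.28, the growth factor gene Fgf11 by 1.80 ± 0.35. The zinc transporter gene Slc39a9 fell by 1.30 ± 0.15, and Ktn1, which encodes kinectin, by 1.30 ± 0.12. Slc26a7, Kantr and Adora1 were also among the lowest (-1.62, -1.53 and -1.46), and Fam209 among the highest (1.61). Amd2, a copy of an S-adenosylmethionine decarboxylase gene, was listed at 0 in both KO libraries and at 23.8, 21.9 and 30.3 in WT, and the defensin gene Defb46 was listed at 0 in KO and at 11.5, 6.32 and 12.3 in WT. The replication-dependent histone genes H4c2, H4c3, H2ac11, H2bc11, H3c3, H4c9 and H3c1 were among the highest as well (1.97 to 3.43). Histone genes, Eno1b, Amd2 and many ribosomal protein genes share reads with near-identical copies. Snora64 (3.14 ± 0.84) and Snord15b (-2.27 ± 0.56) lie inside other genes. The values of all of these are uncertain.

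At 3 dpp, 695 genes were higher and 1125 lower in KO (1820 of 17746), 265 of them provisional models, and 113 and 146 changed at least 2-fold. The count was 653 without KO 18, 942 without WT 13 and 862 without WT 14. It was 72 in a fit of the 5 libraries of this age alone (41 higher and 31 lower) and 559 after each library's trends with transcript length and GC content were removed. With lengths and GC contents permuted among genes, which keeps the centring of the libraries, it was 1101 to 1147. With rescaled values 302 genes were higher and 2960 lower.

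At 7 dpp far fewer genes passed: 18 were higher and 10 lower in KO, 7 of them provisional models. Ptk2b rose by 2.83 ± 0.22, the RCC1-like repeat gene Rcbtb2 by 1.43 ± 0.17, the RNA-binding factor gene Rtraf by 1.25 ± 0.20. Baiap2l1, a regulator of actin at membranes, rose by 1.69 ± 0.29, Myh6, a myosin heavy chain, by 0.98 ± 0.16, the nucleotide phosphatase gene Entpd4 by 0.91 ± 0.10 and the HMG-box gene Tox4 by 0.66 ± 0.11. Eno1b, Tktl2 and Lpl fell by 5.18 ± 0.30, 3.79 ± 0.21 and 2.31 ± 0.28. Ndufb7 fell by 1.2 ± 0.08 (from 458 ± 44.7, n = 2, to 199 ± 18.5, n = 3), the meiotic crossover gene Ccnb1ip1 by 0.86 ± 0.13 and Neto2 by 0.82 ± 0.13. The histone genes H4c3, H2bc11, H3c3 and H4c9 rose by 1.91 to 3.99, and H4c2 was listed at 0 in both WT libraries and at 9.92, 29.7 and 22.4 in KO. The count fell to 13 without WT 3 or KO 6 and to 18 without WT 2, and rose to 106 without KO 4. A fit without chromosomes 8 and 14 called 12. The split turned to 10 higher and 16 lower without a filter, to 8 and 9 without the mean-variance trend, and to 6 and 7 and 9 and 10 without WT 3 and KO 5.

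Among the gene lists called at 7 dpp, oxidative phosphorylation held 1 gene that passed over all genes in limma (Ndufb7, lower) and the others 0. Their medians lay between -0.12 and 0.71, apart from that of erythroid cells (2.66). Genes of undifferentiated spermatogonia lay above WT in 24 of 29 cases (median 0.52, camera adjusted p = 1.45e-08, and adjusted p = 0.31 with an estimated correlation). Of these, 10 were higher when adjusted over the list alone. Its members with the smallest p were Pax7, which marks a rare stem-like fraction (signal 0.934 ± 0.241 in WT and 2.46 ± 0.694 in KO), Cdh1, Dusp6 and Zbtb16, with log2 differences of 0.82, 0.93, 0.85 and 0.52. Immediate early and dissociation stress genes were higher too in 15 of 17 cases (median 0.71, 2 over the list alone, camera adjusted p = 1.45e-08, and adjusted p = 0.31 with an estimated correlation). Egr1 had a signal of 152 ± 6.99 in WT and 257 ± 55.4 in KO, and Socs3 lay 1.02 ± 0.21 above WT. In limma 0 genes of these lists passed over all genes, in which 1328 of 17746 genes had an unadjusted p under 0.05. The scores of the undifferentiated list were -0.39 and -0.03 in WT and -0.14, 0.59 and 0.48 in KO.

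The other 11 lists called at 7 dpp each lost the call when at least 1 library was left out, and their adjusted p ran from 0.31 to 0.82 with an estimated correlation. Higher were erythroid cells (3 genes tested, median 2.66, but 0.20 and adjusted p = 0.12 without a filter, with Hbb-b1 and Hba-a1 2.67 ± 0.93 and 2.66 ± 1.00 above WT), endothelial cells (0.30), Sertoli cells (0.28), peritubular myoid cells (0.26) and lysosome and autophagy (0.10). Lower were sterol and fatty acid synthesis (-0.12), differentiating spermatogonia (-0.12), meiotic prophase (-0.11), ribosome biogenesis (-0.08), cytosolic ribosomal proteins (-0.07) and oxidative phosphorylation (-0.06). The Sertoli median was -0.02 without WT 3 (adjusted p = 0.92), and the ribosomal protein median was 0.04 without WT 3 and 0.03 without KO 4. Without WT 3 the calls of all 11 but lysosome and autophagy and endothelial cells ended (adjusted p = 0.056 to 0.94). Without KO 4 all but lysosome and autophagy, differentiating spermatogonia and meiotic prophase ended (0.083 to 0.73). Without WT 2 those of lysosome and autophagy, differentiating spermatogonia and endothelial cells ended (0.36, 0.076 and 0.31), and without KO 5 those of differentiating spermatogonia, meiotic prophase and endothelial cells (0.35, 0.074 and 0.1). Without KO 6 those of sterol and fatty acid synthesis, oxidative phosphorylation and differentiating spermatogonia ended (0.17, 0.058 and 0.17). Quantile normalization ended the calls of sterol and fatty acid synthesis, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation and differentiating spermatogonia (0.11 to 0.77). A stricter filter ended those of sterol and fatty acid synthesis, differentiating spermatogonia, Sertoli cells and endothelial cells (0.061 to 0.26). A pseudocount of 0.1 or rescaled values ended that of Sertoli cells (0.075 and 0.062), and a fit of the libraries of this age alone that of sterol and fatty acid synthesis (0.056). Removal of the length trend ended those of differentiating spermatogonia and erythroid cells (0.055 for both), and removal of length and GC trends those of meiotic prophase and erythroid cells (0.099 and 0.07). Of the 26 mTOR pathway components, Akt1s1 alone passed at 7 dpp and in adults.

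In adults, 22 genes were higher and 26 lower in KO, 12 of them provisional models. Ptk2b, Rcbtb2, Rtraf, Entpd4 and Myh6 rose in adults, by 2.69 ± 0.22, 1.42 ± 0.17, 1.40 ± 0.20, 0.95 ± 0.10 and 0.87 ± 0.16. So did the chromatin gene copy Morf4l1b (1.59 ± 0.24), the zinc finger gene Zfp868 (0.98 ± 0.11), Pop1, a subunit of RNase P and MRP (0.95 ± 0.12), the proteasome subunit gene Psmb5 (0.92 ± 0.13), the mitochondrial ribosomal protein gene Mrpl39 (0.82 ± 0.11) and Osgep, a tRNA modification enzyme (0.77 ± 0.12). Lower were Eno1b (-4.24 ± 0.30), Tma7 (-2.36 ± 0.38), Tktl2 (-2.30 ± 0.21), the membrane protein gene Emp3 (-1.64 ± 0.29), the synaptic organiser gene Cbln1 (-1.36 ± 0.23), and Ktn1 (-1.21 ± 0.12). Rex2 (-0.95 ± 0.13), Gcdh, an enzyme of lysine breakdown (-0.95 ± 0.16), the ADP/ATP carrier gene Slc25a4 (-0.83 ± 0.13), the methionine salvage gene Mri1 (-0.83 ± 0.15) and Arhgef3 (-0.82 ± 0.15) were lower as well. Ndufb7 fell by 0.56 ± 0.08, and Defb46 was listed at 0 in KO and at 9.33 and 8.40 in WT. Leaving out KO 10 raised the count from 48 to 796 (52 higher and 744 lower) and leaving out WT 9 raised it to 158. It was 16 without WT 7, 27 without KO 11 and 28 without KO 12. Without chromosomes 8 and 14 it was 18, and in a fit of the adult libraries alone 19 (14 higher and 5 lower). Without the mean-variance trend 17 were higher and 14 lower. With the length trend removed 19 genes were higher and 15 lower.

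Transcripts of spermatids, macrophages, Leydig cells and Sertoli cells were lower in the adult KO libraries as lists, although 0 of their genes passed singly over all genes in limma (2094 of 17746 genes had an unadjusted p under 0.05). All 29 genes of round and elongating spermatids lay below WT (median -1.0, 15 lower when adjusted over the list alone, camera adjusted p = 1.79e-09, and adjusted p = 0.56 with an estimated correlation). Prm2, a protamine that packs sperm DNA, had a signal of 3306 and 1564 in WT and of 1486, 640 and 659 in KO. Macrophage genes were lower (median -2.23, 10 over the list alone, camera adjusted p = 3.35e-08, adjusted p = 0.52 with an estimated correlation), with Csf1r, the receptor for macrophage growth factors, at 66.8 ± 46.2 in WT and 14.4 ± 15.3 in KO. Leydig cell genes (median -1.79, camera adjusted p = 0.00601, with 0.62 as adjusted p with an estimated correlation) and Sertoli cell genes (median -0.60, 1 over the list alone, camera adjusted p = 0.000142, and 0.6) were lower as well. The Leydig median was -0.70 without KO 11 (adjusted p = 0.076) and the Sertoli median -0.36 without WT 7 (0.064). The lists of peritubular myoid cells (-0.21), stromal fibroblasts (-0.20), endothelial cells (-0.22) and erythroid cells (-0.93) did not pass (camera adjusted p = 0.484, 0.681, 0.38 and 0.38). Immediate early and dissociation stress genes lay below WT (median -0.84, 9 over the list alone, camera adjusted p = 1.28e-07, and adjusted p = 0.52 with an estimated correlation), for instance Egr1 (-0.73 ± 0.20) and Hspa1a (-0.84 ± 0.23). The spermatid score was 3.64 and 2.92 in WT and 3.18 in KO 10, 2.07 in KO 11 and 2.14 in KO 12. The macrophage score was 3.81 and 2.37 against 2.37, -0.19 and 1.06, KO 10 being nearest to WT in both.

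Proliferative and meiotic transcripts were slightly higher in the adult KO libraries as lists. The signal is relative to the other transcripts of a library, and the spermatid, macrophage and Leydig cell lists were lower in these libraries. More proliferative or meiotic transcripts per germ cell therefore cannot be inferred. The cell cycle list lay above WT in 26 of 27 genes (median 0.14, camera adjusted p = 3.93e-07, adjusted p = 0.56 with an estimated correlation). The meiotic prophase list lay above WT in 26 of 31, with Smc1b and Dmc1 both 0.34 above WT (median 0.14, camera adjusted p = 2.14e-05, adjusted p = 0.5 with an estimated correlation). No member passed over all genes in limma. Oxidative phosphorylation (median 0.09) and ribosomal proteins (0.08, with a mean of 0.00) were called higher, and undifferentiated spermatogonia (-0.34), glycolysis (-0.29, 1 over the list alone) and lysosome and autophagy (-0.10, 7 over the list alone) lower, with adjusted p from 0.56 to 0.67 with an estimated correlation. These 5 calls each ended without at least 1 library. Without WT 7 the ribosomal protein median turned to -0.01 (adjusted p = 0.78) and oxidative phosphorylation had adjusted p = 0.07. It was 0.66, 0.066 and 0.068 for undifferentiated spermatogonia without WT 9, KO 10 and KO 12, 0.11 and 0.058 for glycolysis without WT 9 and KO 12, and 0.17 and 0.1 for lysosome and autophagy without WT 7 and KO 10. Ribosomal proteins also lost the call without KO 11 (0.15), quantile normalization ended that of oxidative phosphorylation (0.46), and removing the length trend or length and GC trends turned the lysosome median to 0.01 or 0.03 and ended its call (0.075 and 0.18).

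A core of genes differed between KO and WT at every age. In limma 17 genes passed at all 3 ages, each in the same direction, and 6 of these were provisional models. The others were Ptk2b, Myh6, Rtraf, Tox4, Entpd4, Rcbtb2 and H4c9, higher in KO, and Akt1s1, Ndufb7, Eno1b and Tktl2, lower in KO. All 18 genes called higher at 7 dpp were also called higher at 3 dpp (0.7 for independent lists), as were 9 of the 10 called lower (0.63). Of the genes called in adults, 18 of the 22 higher and 15 of the 26 lower were called likewise at 3 dpp (0.86 and 1.65). The groups of different ages share no libraries, but they share the mouse lines. In the model they also share a single estimate of the spread per gene, so a gene with a small spread tends to pass at several ages. The numbers for independent lists are therefore a low reference.

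Averaged over the ages, 112 genes were higher and 141 lower in KO, 62 of them provisional models. Besides Ptk2b (2.71 ± 0.13), Rtraf (1.40 ± 0.12) and Rcbtb2 (1.35 ± 0.10), Baiap2l1 rose by 1.29 ± 0.17 and Haus4, which augments spindle microtubules, by 0.97 ± 0.07. The histone genes H2bc11, H4c3, H4c9, H3c3, H2ac11 and H3c1 rose by 1.5 to 3.12, and H4c2 (3.53 ± 0.38) was listed at 0 in WT libraries of 7 dpp. Lower were Eno1b (-4.93 ± 0.17), Tktl2 (-3.22 ± 0.12), Lpl (-1.71 ± 0.16), Tma7 (-1.37 ± 0.22), the fatty acid binding protein gene Fabp5 (-1.29 ± 0.18) and the lysophospholipid acyltransferase gene Lpcat2 (-1.18 ± 0.17). Also lower were Ktn1 (-1.02 ± 0.07), the protamine gene Prm3 (-0.97 ± 0.21), Cyb5r4 (-0.97 ± 0.22), the sperm chaperone gene Clgn (-0.93 ± 0.15) and Gcdh (-0.86 ± 0.09). Rpl21 fell by 4.61 ± 0.95 (adjusted p = 0.032), but it has many near-identical copies, and its signal in KO ranged from 0.33 to 80.4 between libraries. Lamtor1 rose by 0.45 ± 0.08 and Acaca fell by 0.27 ± 0.05. Among lists, ribosomal proteins (median 0.14) and oxidative phosphorylation (0.15) were called higher and spermatids (-0.26) and Sertoli cells (-0.33) lower, with adjusted p = 0.82, 0.7, 0.85 and 0.85 with an estimated correlation. With the 3 dpp libraries left out, the first pair had medians of 0.00 (adjusted p = 0.53 for both) and the Sertoli median was -0.19 (0.16). Quantile normalization lowered the ribosomal protein median to 0.03 and ended its call (0.098), and the oxidative phosphorylation median to 0.06 (0.0029). Rescaled values ended the spermatid and Sertoli calls (0.076 for both) at medians of -0.30 and -0.39, and a pseudocount of 0.1 ended the spermatid call (0.063). Without WT 7 of the adults the spermatid and Sertoli calls ended, at medians of -0.13 and -0.25 (adjusted p = 0.19 and 0.15). The Sertoli call also ended without KO 16 (median -0.11, 0.77) or WT 2 (0.13) and the spermatid call without KO 16 (0.052), KO 11 (0.081) or KO 12 (0.058).

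The genes called in the averaged comparison gathered on a pair of chromosomes. Of 197 called genes with a known position, 76 (38.6%) lay on chromosome 8 or 14, which hold 8.72% of the tested genes (17.2 expected, Fisher's exact test, two-sided, p = 8.57e-31), with 40 higher and 36 lower in KO. They included Tktl2, Lpl, Ndufb7 and Gcdh on chromosome 8 and Ptk2b, Rtraf, Ktn1, Psmb5, Tox4 and Myh6 on chromosome 14. At 7 dpp 13 of 21 and in adults 22 of 36 called genes with a position lay there, and at 3 dpp 175 of 1612 (141 expected). Without these chromosomes 123 genes passed in the averaged comparison, and 71 passed with the 3 dpp libraries left out. The averaged count was 139 without WT 2, 148 and 152 without WT 7 and WT 9, 165 and 164 without KO 11 and KO 12, and 411 without KO 16. The split of 112 higher and 141 lower was 161 and 132 with quantile normalization, 104 and 327 with rescaled values, 88 and 55 with the length trend removed, and 92 and 56 with length and GC trends removed.

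**Figure D2:**
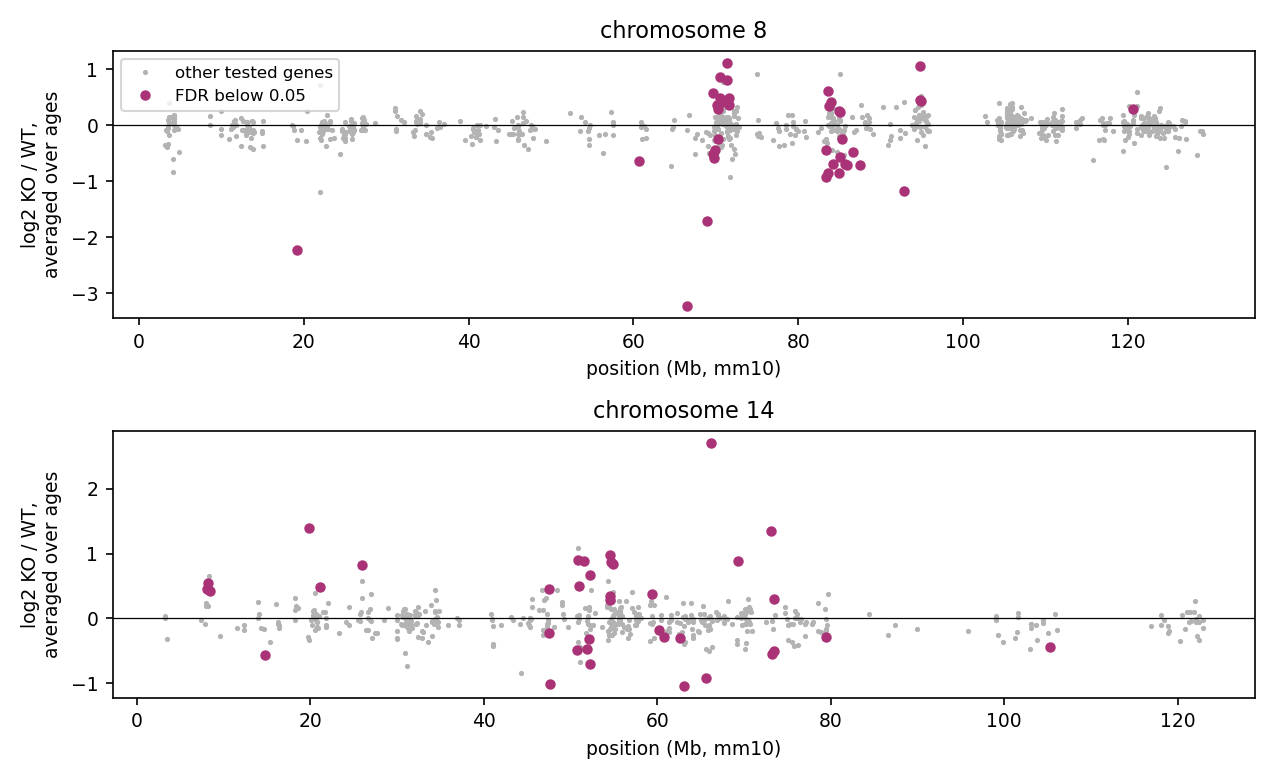
Averaged log2 difference of KO against WT (vertical axis) of the tested genes along chromosomes 8 and 14 (position in Mb, mm10), with genes that passed in purple and other tested genes in grey. The 40 higher and 36 lower genes include 37 of 39 calls of chromosome 8 between 60 and 95 Mb, where 275 of its 798 tested genes lie, and 36 of 37 calls of chromosome 14 between 8 and 80 Mb, which holds 466 of its 522 tested genes.

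From 3 to 7 dpp in WT cells, genes of differentiating spermatogonia rose as a list, and those of undifferentiated spermatogonia were called lower with members moving both ways. Genes of differentiating spermatogonia rose in 9 of 12 cases and fell in 1 (also over the list alone, median 1.02, camera adjusted p = 3.22e-06, and adjusted p = 0.3 with an estimated correlation). The receptor gene Kit went from a signal of 50.2 ± 4.26 to 137 ± 2.46 (log2 change 1.43 ± 0.15), and the retinoic acid target Stra8 (1.63 ± 0.18) and the transcription factor gene Sohlh1 (0.93 ± 0.09) rose as well, whereas Ccnd2 fell by 1.69 ± 0.19. Of 29 genes of undifferentiated spermatogonia, 14 fell and 5 rose (16 and 6 over the list alone, median -0.73, camera adjusted p = 0.00395, and adjusted p = 0.77 with an estimated correlation). The stem cell transcription factor genes Lhx1 and Eomes fell by 4.40 ± 0.51 and 2.40 ± 0.28 and Cdh1 by 2.32 ± 0.27, while Neurog3, which marks progenitors primed to differentiate, rose by 3.58 ± 0.42. Prospermatogonial genes moved both ways (3 up and 3 down of 10), with Dppa3 up by 2.91 ± 0.41, Pou5f1 up by 1.95 ± 0.38 and Etv4 down by 3.26 ± 0.53.

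The cell cycle list of WT cells fell in 11 of 27 genes (15 over the list alone, median -0.30, camera adjusted p = 7.22e-05, and adjusted p = 0.77 with an estimated correlation), with the S phase genes Ccne1 and Rrm2 down by 1.12 ± 0.11 and 1.02 ± 0.18. The glycolysis list fell in 7 of 17 genes (8 over the list alone, median -0.54), including Hk2 (-0.92 ± 0.15) and Pfkp (-1.16 ± 0.26). The immediate early list fell in 6 of 17 with 2 up (median -0.89), including Egr1 (-1.22 ± 0.20) and Socs3 (-1.37 ± 0.21), both lists with adjusted p = 0.77 with an estimated correlation. The glycolysis call ended without WT 2 (adjusted p = 0.054) and the immediate early call without WT 13 (0.087) or WT 3 (0.076).

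Other genes changed in WT cells over this interval without a call of their list. In the mTOR pathway Akt1 and Ddit4, a stress-induced inhibitor of mTORC1, rose by 0.85 ± 0.12 and 1.53 ± 0.29 and Rps6kb2 fell by 1.13 ± 0.19 (2 up and 2 down of 26). The p53 target Cdkn1a fell by 2.29 ± 0.27 (3 up and 2 down of 14). Tbx1, Lhx8, Dlx1, Cldn11, Rln3 and Upp1 rose by 1.98 to 2.88, and Nefm, Tmc8, Arhgap9, Sez6, Elfn1, Nxph4 and Plaur fell by 3.44 to 4.39. In all, 1375 genes rose and 1855 fell. The count of 3230 was 1467 without WT 2, 2030 without WT 3 and 1963 without WT 14. With length or length and GC trends removed the genes split into 1665 and 1423 or 1810 and 1474.

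From 7 dpp to the adult, the spermatid and macrophage lists rose in the WT sorts, and those of ribosomal proteins and Sertoli cells fell. Of 29 spermatid genes 28 rose and 0 fell (29 over the list alone, median 4.12), led by Prm2 (9.03 ± 0.46), Tnp2 (9.01 ± 0.51), Smcp (8.19 ± 0.44), Prm1 (8.10 ± 0.54) and Crisp2 (7.06 ± 0.38), which serve chromatin packing and sperm structure. All 12 macrophage genes rose (median 4.71), such as C1qa (6.06 ± 0.85) and Csf1r (5.50 ± 0.80). Of 12 Leydig cell genes 4 rose, among them Insl3 (8.83 ± 1.77) and the steroidogenic Hsd3b6 (5.80 ± 0.91), although the Leydig list did not pass (camera adjusted p = 0.116). Stromal fibroblasts (0 up and 2 down of 11, median -0.55, camera adjusted p = 0.0528), peritubular myoid cells (1 up and 1 down of 9, median -0.11, 0.877) and endothelial cells (0 of 7, median 0.14, 0.877) did not pass either. Of 19 Sertoli cell genes 12 fell and 2 rose (13 and 2 over the list alone, median -2.21), with Amh, Rhox8 and Dhh down by 5.76 ± 0.52, 3.99 ± 0.40 and 3.36 ± 0.45. Ribosomal protein genes fell in 61 of 75 cases (70 over the list alone, median -0.66), for example Rpsa, from 2288 ± 273 to 945 ± 100 (-1.27 ± 0.13). Ribosome biogenesis genes fell in 22 of 30 (25 over the list alone, median -0.47, with Dkc1 at -0.78 ± 0.10 and Npm1 at -0.89 ± 0.15) and genes of sterol and fatty acid synthesis in 13 of 26 with 2 up (16 and 2 over the list alone, median -0.44, with Msmo1 at -1.48 ± 0.23). Each of these called lists had adjusted p = 0.39 with an estimated correlation. Oxidative phosphorylation fell in 28 of 75 genes (29 over the list alone, median -0.30, and adjusted p = 0.39 with an estimated correlation), for example Uqcrb (-0.78 ± 0.13), but with quantile normalization its median was -0.07 (0.47).

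Undifferentiated spermatogonia genes fell in 3 of 29 cases in adult WT sorts (1 over the list alone, median -0.38), Dusp6 by 1.21 ± 0.29, and cell cycle genes fell in 8 of 27 with 2 up (10 and 2 over the list alone, median -0.26), both with adjusted p = 0.7 with an estimated correlation. The first call ended without WT 3 (adjusted p = 0.25) or WT 7 (0.30) and under quantile normalization (0.23), which also ended the second (0.50). The first ended too with a stricter filter (0.11), with the length trend removed (0.15) and with length and GC trends removed (0.1). Single genes of other lists rose, such as Esx1 (2.27 ± 0.29) and Prss50 (3.45 ± 0.43) of differentiating and Meioc (1.36 ± 0.24) of meiotic cells. Lcn2 and Gsg1 rose by 7.77 ± 0.92 and 7.21 ± 0.39, while Ccn1, Edn1, Capn6, Aard and Hsd17b1 fell by 3.32 to 5.11. In all 3157 genes rose and 2169 fell. The count of 5326 was 2514 without WT 7. The split was 2467 and 3369 with quantile normalization, 4580 and 1150 with rescaled values, 2053 and 4370 with the length trend removed and 1995 and 4419 with length and GC trends removed. These moved the median of all genes to -0.12, 0.21, -0.19 and -0.19. Removal of a trend also centres each library, so its share in these shifts cannot be told apart from that of length.

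**Figure D3:**
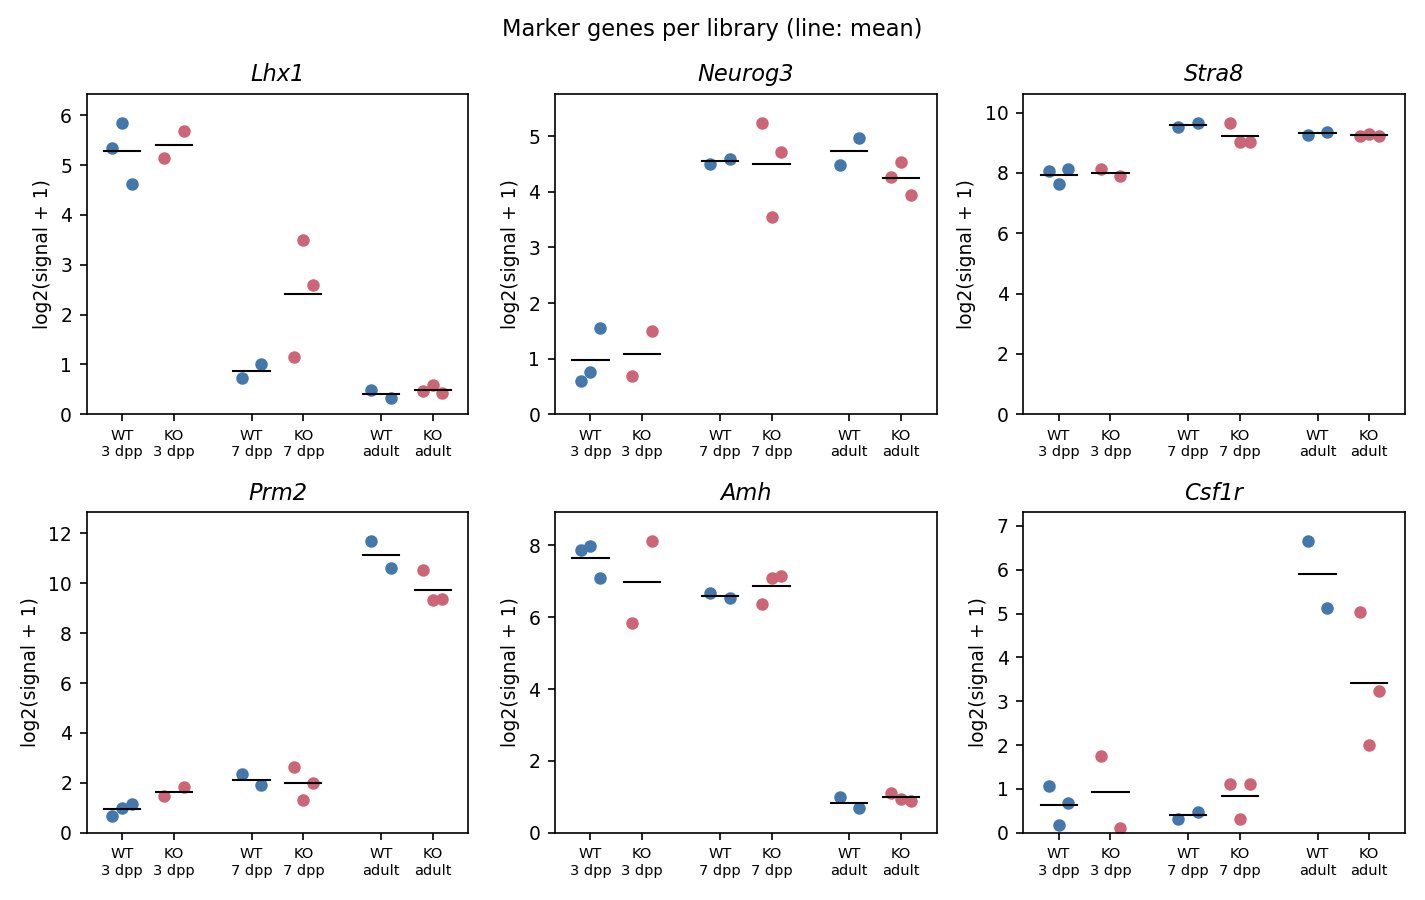
log2(signal + 1) of Lhx1, Neurog3, Stra8, Prm2, Amh and Csf1r (vertical axes) in each library by age and genotype, with a line at the group mean. Neurog3 and Stra8 are higher at 7 dpp than at 3 dpp, Lhx1 is lower, Amh is lowest in adults, Prm2 has a signal of 640 to 3306 in adult libraries and of at most 5.22 in younger ones, and Csf1r of 2.99 (KO 11) to 99.5 in adult and of at most 2.36 in younger ones.

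Between 3 and 7 dpp, the lists of differentiating spermatogonia, glycolysis and the cell cycle were called in KO in the same direction as in WT, while those of undifferentiated spermatogonia and immediate early genes, called in WT, did not pass in KO. Differentiating spermatogonia genes rose in 7 of 12 cases and fell in 1 (8 and 2 over the list alone, median 0.64, camera adjusted p = 0.00999, and adjusted p = 0.74 with an estimated correlation). Kit rose by 1.34 ± 0.15, Stra8 by 1.22 ± 0.18 and the retinoic acid receptor gene Rarg by 2.08 ± 0.25. Neurog3, Cldn11 and Basp1 rose by 3.41 ± 0.42, 3.04 ± 0.50 and 2.85 ± 0.42, Dppa3, Amd2 and Defb46 rose from libraries listed at 0. The stem cell genes Id4 and Bcl6b fell by 2.52 ± 0.36 and 1.90 ± 0.30, but with 13 genes down and 8 up of 29 the undifferentiated list did not pass (median -0.49, camera adjusted p = 0.293). The immediate early list had 3 genes up and 0 down of 17 (median 0.06, camera adjusted p = 0.703), and whether these lists differ between genotypes was not tested. Ribosomal protein genes fell in 36 of 75 cases (45 over the list alone, median -0.37, which turned to 0.01 with quantile normalization, adjusted p = 0.63), with Rpl29 at -0.71 ± 0.12. Oxidative phosphorylation genes fell in 45 of 75 (53 over the list alone, median -0.42), with Atp5j at -0.91 ± 0.09. Both lists had adjusted p = 0.74 with an estimated correlation. Of 26 mTOR pathway components 10 rose and 5 fell (also over the list alone), including Ddit4 (2.19 ± 0.29), Rptor (0.75 ± 0.11) and Mtor (0.58 ± 0.09). The list did not pass (camera adjusted p = 0.268).

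Cell cycle genes of KO cells fell in 13 of 27 with 3 up (14 and 4 over the list alone, median -0.28, and adjusted p = 0.93 with an estimated correlation). Glycolysis genes fell in 5 of 17 with 1 up (6 and 1 over the list alone, median -0.39, and adjusted p = 0.74 with an estimated correlation). Sertoli cell genes rose in 9 of 19 with 2 down (11 and 2 over the list alone, median 1.04, and adjusted p = 0.93 with an estimated correlation). Without KO 16 the Sertoli median was 0.36 (adjusted p = 0.80) and the cell cycle call ended (0.15), and quantile normalization ended the glycolysis and cell cycle calls (0.097 for both). Removal of length and GC trends ended the glycolysis call (0.11), and a stricter filter or rescaled values the Sertoli call (0.081 and 0.077).

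Among the lowest genes of KO cells from 3 to 7 dpp were Gngt2, Abi3, Nxph4, S100a6 and Plaur (-3.57 to -3.35) and Tom1 (-3.48 ± 0.79). Rmrp, a noncoding RNA without a poly(A) tail, had a signal of 53.9 and 3707 in the KO libraries of 3 dpp and fell by 4.38 ± 1.24, and Snord15b, Snord32a and Snora64 (3.01, 2.74 and -3.28) are small RNAs within other genes. In all 2897 genes rose and 2438 fell. The count of 5335 was 3382 without KO 18 and 2977 in a fit of these libraries alone. With rescaled values, which shifted the median of all genes to 0.17, 4817 rose and 1375 fell. Of the genes higher and lower at 7 dpp in WT, 812 and 1024 were called likewise in KO (224 and 255 for independent lists), and 16 and 28 were called in the opposite direction. Both genotypes share the estimate of the spread per gene, so the numbers for independent lists are a low reference. Across genes, which are not independent replicates, the changes of both genotypes correlated with r = 0.59 for this interval and 0.86 from 7 dpp to adults.

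From 7 dpp to adults, KO sorts gained spermatid transcripts in 29 of 29 genes (median 3.45), with Prm2, Tnp2, Prm1, Smcp, Crisp2 and Tnp1 up by 5.92 to 7.76. Meiotic prophase transcripts rose in 16 of 31 genes (median 0.39), including the meiotic entry regulators Meioc (1.97 ± 0.20) and Ythdc2 (1.09 ± 0.12) and the recombination gene Prdm9 (1.99 ± 0.24). Undifferentiated spermatogonia genes fell in 22 of 29 cases (median -1.09), among them Dusp6 (-2.98 ± 0.24), the GDNF receptor gene Ret (-2.19 ± 0.31) and Bcl6b (-1.94 ± 0.27). Sertoli cell genes fell in 17 of 19 with 1 up (median -2.66), with Amh, Rhox8, Aard and Dhh down by 4.34 to 5.89. These counts were the same over the list alone, and each list had adjusted p = 0.33 with an estimated correlation. Macrophage genes rose in 9 of 12 cases (10 over the list alone, median 2.16, and adjusted p = 0.42 with an estimated correlation), with C1qa up by 2.90 ± 0.69.

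Ribosomal protein genes of KO sorts fell in 61 of 75 cases (66 over the list alone, median -0.54), immediate early genes in 11 of 17 (12 over the list alone, median -0.76, Egr1 by 2.29 ± 0.18). Glycolysis genes fell in 10 of 17 with 1 up (median -0.38, Pkm by 1.71 ± 0.17) and amino acid stress response genes in 9 of 19 with 1 up (median -0.19, Phgdh by 1.22 ± 0.18), all 4 lists with adjusted p = 0.38 with an estimated correlation. Ribosome biogenesis fell in 20 of 30 (22 over the list alone, median -0.35) and sterol and fatty acid synthesis in 15 of 26 with 1 up (16 and 2 over the list alone, median -0.34, Scd2 by 1.76 ± 0.14). Stromal fibroblast genes fell in 5 of 11 (6 over the list alone, median -0.70, Sparc by 3.28 ± 0.51), these 3 lists with adjusted p = 0.42 with an estimated correlation.

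Oxidative phosphorylation genes fell in 23 of 75 cases and rose in 2 in adult KO sorts (21 and 1 over the list alone, median -0.12, and adjusted p = 0.51 with an estimated correlation), but the median turned to 0.04 with quantile normalization. With rescaled values it was 0.06, below the 0.18 of all genes, and the call ended (adjusted p = 0.12). Quantile normalization also ended the amino acid stress response call (adjusted p = 0.053), and a stricter filter that of the stromal fibroblasts (0.052). The hemoglobin genes Hba-a1 and Hbb-b1 fell by 3.99 ± 0.89 and 3.70 ± 0.84, and of 12 Leydig cell genes 2 rose and 3 fell. Lcn2 and Gsg1 rose by 6.13 and 6.10, Ccn1, Edn1, Etd and Inha fell by 4.20 to 6.35. Pou5f1 fell by 1.12 ± 0.34, while in WT its difference of -1.13 ± 0.41 did not pass (adjusted p = 0.0543). In all 3945 genes rose and 3646 fell, against 5762 and 2496 with rescaled values (median of all genes 0.18), 2915 and 4112 with the length trend removed and 2956 and 4217 with length and GC trends removed. Of the genes called in WT over this interval, 2413 rose and 1711 fell in both genotypes (702 and 446 for independent lists), and 13 and 3 went opposite ways. As for the earlier interval, the numbers for independent lists are a low reference, since the estimate of the spread is shared.

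**Figure D4:**
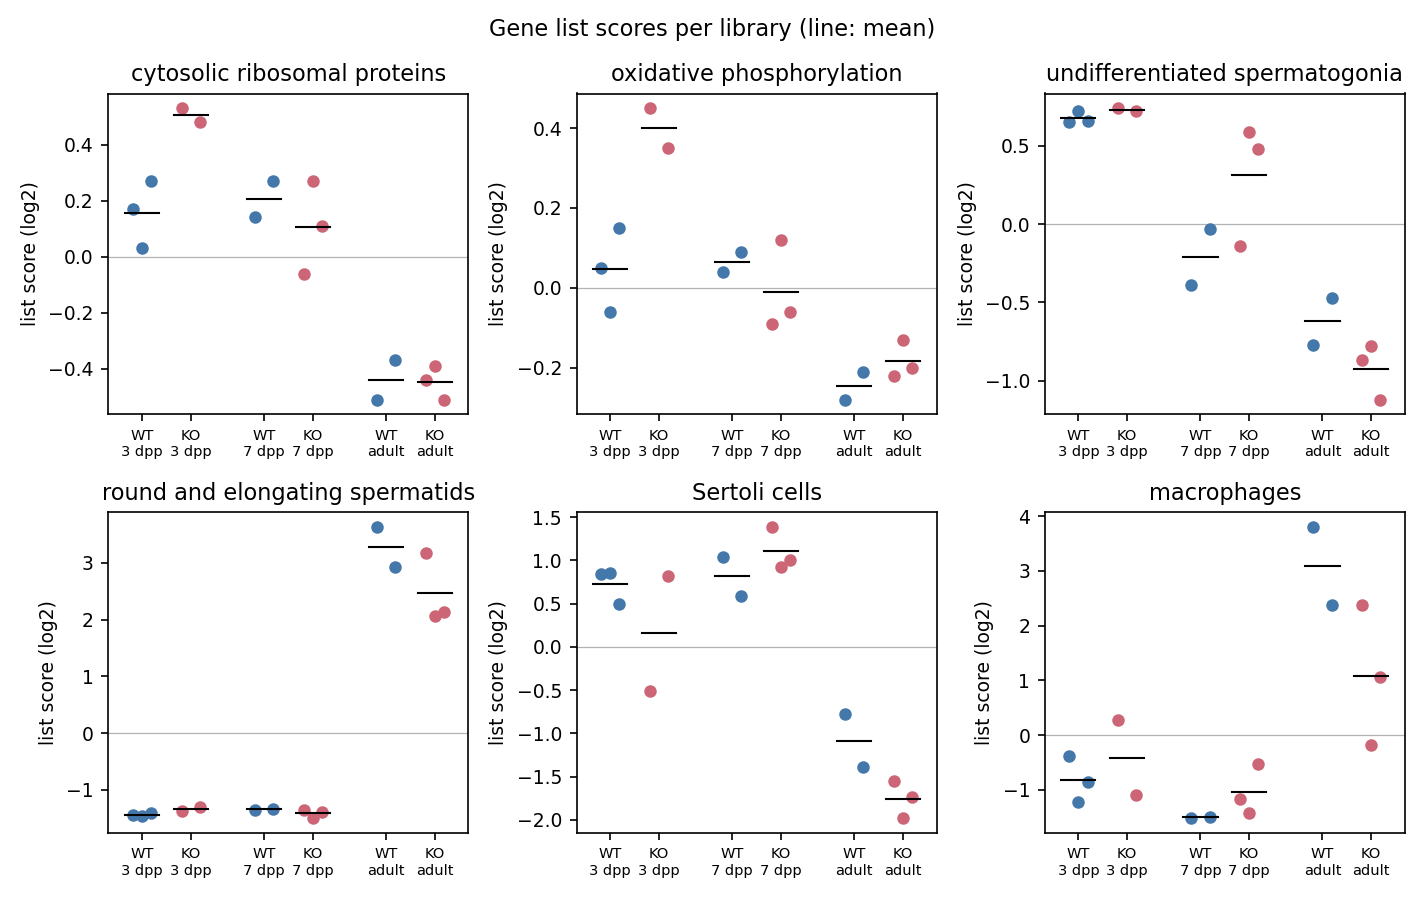
Scores of 6 gene lists (log2, vertical axes; ribosomal proteins, oxidative phosphorylation, undifferentiated spermatogonia, spermatids, Sertoli cells and macrophages) in each library by age, WT in blue and KO in red, with a line at the group mean. At 3 dpp both KO libraries lie above the WT libraries for ribosomal proteins (0.53 and 0.48 against 0.03 to 0.27) and for oxidative phosphorylation. Quantile normalization, which can remove a shift shared by genes of high signal, takes the median change of the ribosomal protein list to 0.00.

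Whether the effect of the genotype differed between ages was tested directly per gene. Between 7 and 3 dpp it differed for 355 genes, 251 of which had a higher KO-to-WT difference at 7 dpp and 104 a lower one. Irs2, an adaptor of insulin signalling, and the phosphatase gene Ptpn3 had differences of 1.59 ± 0.32 and 1.51 ± 0.32, Kctd14 of 1.68 ± 0.33. Tom1, Fam209, Calr3 and Alkbh3 had differences of -5.59 ± 1.12, -2.60 ± 0.48, -1.5 ± 0.27 and -1.17 ± 0.20. Between adults and 3 dpp the effect differed for 179 genes, with 132 higher in adults and 47 lower. Meioc, Slc39a9, the kinetochore gene Knl1 and Ubr3 had differences of 1.64 ± 0.31, 1.57 ± 0.22, 1.40 ± 0.21 and 1.25 ± 0.22, and Gsg1, Hoxb2, Cdc42ep3 and Ndrg2 of -2.37 ± 0.51, -2.06 ± 0.43, -1.96 ± 0.40 and -1.79 ± 0.38. Between adults and 7 dpp 0 genes passed in limma (smallest adjusted p = 0.195), with 2190 genes at an unadjusted p under 0.05, 4 genes passing without a filter, 1 with a pseudocount of 0.1 and 0 without the mean-variance trend. The genes with the smallest p in this contrast were Lpl (2.14 ± 0.39), Tktl2 (1.49 ± 0.29), Ndufb7 (0.64 ± 0.12), Slc25a4 (-1.19 ± 0.18), Zfp703 (-1.22 ± 0.22) and Sgk1 (-0.84 ± 0.15). The effect on Akt1s1 did not differ between ages by this test (adjusted p = 0.692, 0.779 and 0.983), and differences of gene lists between ages were not tested.

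These interaction counts depended on the processing and on single libraries. The 355 genes between 7 and 3 dpp became 8 in a fit of only the libraries compared, 63 without the mean-variance trend, and 17 and 20 with length and with length and GC trends removed. The 179 genes between adults and 3 dpp became 114, 19, 121 and 17. That between 7 and 3 dpp was 24, 58, 143, 26 and 40 without WT 14, WT 13, KO 18, WT 3 and KO 6, and 967 and 676 without WT 15 and KO 16. That between adults and 3 dpp was 51, 23 and 99 without WT 13, WT 14 and WT 15, 23, 13, 26, 30 and 18 without KO 18, WT 7, WT 9, KO 11 and KO 12, and 554 and 357 without KO 16 and KO 10. That between adults and 7 dpp was 47 without KO 4, 6 without KO 10, 3 without WT 7, 2 without WT 9 and 1 without KO 11. With rescaled values, which moved the median of all genes to 0.21 and 0.13, the first pair split into 1436 higher and 95 lower and into 966 and 74, and with the length trend removed the second split into 102 and 19.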

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

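The interaction contrasts, the random lists matched on length and mean value and the splits of the libraries were planned, whereas the tests of chromosomes, distances between genes, removed trends, rescaled values, pairs of lists and the exact permutation test of the spermatid score were chosen only after the result was seen.

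The effect of the genotype differed between 7 and 3 dpp for 355 genes and between adults and 3 dpp for 179 genes, by the interaction contrasts in limma. In fits of only the libraries compared these counts were 8 and 114, without the mean-variance trend 63 and 19, and with length and GC trends removed 20 and 17. Between 7 and 3 dpp, Amd2 (adjusted p = 0.000736) and Defb46 (adjusted p = 0.0176) differed, both listed at 0 in KO at 3 dpp. Snord15b had a difference of 3.89, Kctd14 of 1.68, Irs2 of 1.59 and Ptpn3 of 1.51, and Tom1 of -5.59, Fam209 of -2.60, H4c4 of -2.18, Calr3 of -1.5, Alkbh3 of -1.17 and Fxyd2 of -1.05. Between adults and 3 dpp, Amd2 differed again (adjusted p = 0.000275), with differences of 2.43 for Fgf11, 1.64 for Meioc, 1.57 for Slc39a9, 1.40 for Knl1 and 1.25 for Ubr3. In the other direction these were -2.37 for Gsg1, -2.06 for Hoxb2, -1.96 for Cdc42ep3, -1.79 for Ndrg2, -1.59 for Dbil5 and -1.25 for Tsacc. These genes were chosen for opposite signs at both ages, and the counts ranged from 24 to 967 and from 13 to 554 when single libraries were left out (24 without WT 14 and 967 without WT 15, 13 without WT 7 and 554 without KO 16). Groups of 2 or 3 libraries are too small for the test of single libraries far from the others.

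The genes called between KO and WT averaged over the ages gathered on chromosomes 8 and 14, with 76 of 197 against 17.2 expected (Fisher's exact test, two-sided, p = 8.57e-31), which argues against loss of Akt1s1 alone as the source of the whole list. Within 20 Mb of Akt1s1 on chromosome 7 lay 4 of the averaged calls (Akt1s1 included), against 5.06 expected, which argues against a passenger region around the deleted gene as the source of this gathering. It does not exclude that such a region adds calls of its own, since 55 lay there at 3 dpp against 41.4 expected (Fisher's exact test, two-sided, p = 0.0299), 1 at 7 dpp against 0.54 (Akt1s1 itself, p = 0.421) and 2 in adults against 0.925 (p = 0.236). The median distance to the nearest other call on chromosomes 8 and 14 was 0.0857 Mb, below all of 10000 random draws (lowest 0.149 Mb), and 26 of 28 genes called there in the younger libraries had the same sign in adults (27 of 35 on other chromosomes). A candidate explanation is that segments of another strain on these chromosomes differ between the WT and KO lines, as might also hold for the histone genes at 21 to 24 Mb of chromosome 13 (9 of 15 calls of that chromosome). Whether such variants would change expression or only the assignment of reads to Ptk2b, Tktl2, Ndufb7 and their neighbours was not tested, and the titles name the WT line Og2 but the strain background of either line is not given in the sources used here.

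At 3 dpp the ribosomal protein and oxidative phosphorylation transcripts were higher in KO and many genes passed. With trends of length and GC content removed the lower of both list medians was still 0.33, random lists matched on length and mean value had a median of 0.20 for ribosomal proteins (0 of 10000 as high as the observed 0.43), and with rescaled values the lower median was 0.19 (list scores 0.16 ± 0.06 and 0.16 ± 0.04 higher, SE, in a test whose bounds were set with these medians known). The lengths are medians over transcripts, so the removed trend can be too weak. The first values therefore cannot exclude length and GC content as the cause. The rescaled values argue against the factor per library as the whole cause. The factor does carry part of the size (medians 0.43 and 0.38 before). The matched lists cannot decide on a trend with length and abundance together, because they were matched only in coarse groups. They also draw genes independently, although the estimated correlation within the ribosomal protein list is 0.54. Matched lists already reach about 0.2, and quantile normalization took the ribosomal protein median to 0.00. Quantile normalization can itself remove a shift shared by genes of high signal, so the 0.00 does not decide whether these genes rose. The number of genes is another matter: it dropped from 1734 of the genes with a known length to 559 with both trends removed, against 1101 to 1147 with permuted lengths and GC contents, so a part of the 1820 calls may come from a length and GC bias of the 2 KO libraries. Across genes, Spearman's rho of the change with GC content was 0.24 at 3 dpp, 0.26 at 7 dpp, where 28 genes passed, and -0.07 in adults. With length it was -0.29, 0.09 and -0.04, so the GC trend is not particular to 3 dpp. An effect of the genotype on translation and respiration genes, a difference in cell state between the sorts and a difference in library preparation stay open and were not tested.

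In adults, markers of spermatids, macrophages, Leydig cells and Sertoli cells were lower in KO, although the cells had been sorted for GFP. The most abundant transcript of each list by its WT mean had a signal of 2559 ± 1420 (SD) in WT and 989 ± 447 in KO for spermatids (Prm1), 306 ± 229 and 75.7 ± 68.2 for macrophages (Lyz2), 4298 ± 1100 and 1264 ± 1290 for Leydig cells (Insl3), and 184 ± 94.5 and 74.0 ± 35.9 for Sertoli cells (Clu). For the lists that did not pass it was 33.77 and 14.05 for peritubular myoid cells (Actg2) and 57.4 and 26.73 for stromal fibroblasts (Sparc). It was 35.19 and 36.44 for endothelial cells (Egfl7) and 2.966 and 0.5917 for erythroid cells (Hba-a1). A smaller share of all other testis cells in the KO sorts would lower these lists alike, and among 28 pairs of lists the smallest adjusted p was 0.13 (stromal fibroblasts minus macrophages, 1.89 ± 0.55, limma), so this could not be excluded. The exact permutation test of the spermatid score (two-sided, 3 KO against 2 WT libraries, p = 0.3) has 10 splits and a smallest possible p of 0.1, so it decides nothing, and variation between sorts stays open. KO 10 lay near WT and 796 genes passed without it, and fewer spermatids in the KO testis, contamination of the sorts and RNA from other cells cannot be told apart with 5 libraries.

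Other splits of the libraries were compared with the real groups. For KO against WT averaged over the ages, 2 of 100 splits within ages (the real one included) gave as many genes as the 253 of the real groups. This share lies under 0.05, so most random groupings gave fewer calls. The other of these splits called 486, and what its groups have in common was not examined. A grouping other than genotype can thus give more calls, and the splits do not show that genotype is the source of the count. For adult against 7 dpp in KO, 1 of 10 splits, the real one, gave 7591 genes and the highest other gave 1, and 10 splits are too few for a share under 0.05.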

How the results depend on the processing

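Rescaled values, removal of length or length and GC trends, leaving out chromosomes 8 and 14 and leaving out the 3 dpp libraries were tests chosen only after the data were seen, and the other alternatives were planned. No paired analysis was possible because the library numbers are unique across groups. The depth is unknown, so what it limits cannot be said, and where a library left out leaves a group with 1, that library is assumed to vary like the other groups. Except where stated, the cause was not tested.

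The 511 results on named genes followed here are those that passed in the main fit of the same libraries, so a reversal was unlikely from the start. Named genes that did not pass are not among them. None reversed under any alternative, and 475 passed with quantile normalization, 368 of 480 in fits of only the libraries compared and 172 against a fold change of 1.5. Akt1s1 was lower in KO under every alternative. In fits of only the libraries compared its values were -0.56 ± 0.10, -0.69 ± 0.14 and -0.57 ± 0.06 at 3 dpp, 7 dpp and in adults, with adjusted p = 0.062, 0.3 and 0.079. Fewer libraries estimate the spread in these fits, and at 7 dpp the SE was also larger than the 0.10 of the main fit. Against a fold change of 1.5 the values -0.56, -0.69, -0.57 and -0.60 (averaged) did not pass, since they lie near that bound. Without the mean-variance trend -0.69 at 7 dpp (adjusted p = 0.062) and -0.57 in adults (0.093) did not pass, nor did adults with the length trend removed (-0.46, 0.11), with length and GC trends removed (-0.51, 0.065) or without chromosomes 8 and 14 (-0.57, 0.069). Leaving out single libraries, Akt1s1 ranged from -0.60 to -0.52 at 3 dpp, -0.89 to -0.48 at 7 dpp, -0.60 to -0.53 in adults and -0.67 to -0.53 averaged.

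Against a fold change of 1.5, a stricter null by construction, 30 genes passed at 3 dpp, 11 at 7 dpp, 9 in adults and 25 averaged. Under it 220 and 1220 passed for the age steps in WT, 256 and 1668 for those in KO, and 3 and 4 for the interactions of 7 dpp and adults with 3 dpp. In fits of only the libraries compared, 72 passed at 3 dpp, 19 in adults, 2977 for 7 against 3 dpp in KO, and 8 and 114 for these interactions. Without the mean-variance trend, 17 passed at 7 dpp, 31 in adults, and 63 and 19 for the interactions. With rescaled values, 3262 passed at 3 dpp, 431 averaged, and 1531 and 1040 for the interactions. With the length trend removed, 710 passed at 3 dpp, 143 averaged and 17 for the interaction of 7 with 3 dpp. With length and GC trends removed, 559 passed at 3 dpp, 148 averaged, and 20 and 17 for the interactions. Without chromosomes 8 and 14, which hold part of the genes, 12 passed at 7 dpp, 18 in adults and 123 averaged, and 71 passed averaged without the 3 dpp libraries. Without a filter, 73 passed in adults and 4 for the interaction of adults with 7 dpp (0 in the main fit and 1 with a pseudocount of 0.1), and a stricter filter gave 298 for adults with 3 dpp.

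Leaving out single libraries, the counts ranged from 653 (without KO 18) to 1932 (without WT 15) at 3 dpp, 13 (WT 3 or KO 6) to 106 (KO 4) at 7 dpp, 16 (WT 7) to 796 (KO 10) in adults and 139 (WT 2) to 411 (KO 16) averaged. They ranged from 1467 to 3619 and 2514 to 3844 for the age steps in WT, 3382 to 5482 and 6106 to 7466 for those in KO, and 24 to 967, 0 to 47 and 13 to 554 for the interactions of 7 with 3 dpp, adults with 7 dpp and adults with 3 dpp.

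Of the 66 list calls, 0 passed with an estimated correlation and fry called 43 lists, and leaving out single libraries gave 58 to 72. Besides the turns given with the lists above, direction reversed for Sertoli cells at 3 dpp without KO 16 (0.16, range -1.36 to 0.16), ribosomal proteins at 7 dpp without WT 3 (0.04) and without KO 4 (0.03, range -0.14 to 0.04), and oxidative phosphorylation in adults against 7 dpp in KO with quantile normalization (0.04).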
